A study of Glycine max with 4 samples.

How the data were processed

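Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the protein of the soybean gene GLYMA.13G153200 sits on DNA in embryos of the cultivar Williams 82. The embryos were at early maturation and came from seeds that measured 6 to 7 mm, per the labels. Chromatin was fixed with 1% formaldehyde for 10 minutes and sheared to fragments of 100 to 500 bp, per the labels' protocols. It was precipitated with 3 micrograms of an antibody against a peptide, residues 275 to 289 of the protein. Libraries went through 15 cycles of PCR, per the labels' protocols. The series holds 4 samples in 2 groups, namely 2 ChIP samples and 2 input samples of sheared chromatin without precipitation, as 2 biological replicates of each. Peak lists of the 2 ChIP samples were used. Files of the input samples were not used here.

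Bowtie 0.12.7 and MACS3 are named in the submitters' processing notes, with no MACS3 version. The options, the control behind each list and the genome build are not given in the sources used here. Each list is in narrowPeak layout with one list per ChIP replicate, so peaks were called per sample and not on pooled samples, per the peak names. The peak names inside the lists also carry a q threshold of 0.01, and the smallest deposited −log10 q was 2.03 and 2.03 in replicates 1 and 2. The fold enrichment deposited for each peak is a ratio of the ChIP signal at the summit to the caller's local background. The −log10 p and −log10 q of each peak are also the authors' deposited values. The deposited score equals 10 times −log10 q cut to a whole number in 99.97% and 99.99% of peaks and was not used further. The remaining deposited columns give the start, the end and the summit of each peak. The peak names in the first list read ABI5 and BR1, and those in the second read ABI5 and BR3, although the second sample is labelled replicate 2. The lists were assigned by the labels. Fold, −log10 p and −log10 q are the authors' own values per peak and were used to describe, rank and filter peaks.

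MACS writes fold as (k + 1) / (λ + 1), where k is the number of fragments over the summit and λ the local background, and writes p as the Poisson probability of more than k fragments. Both equations were solved for each peak, which gave a whole number k and a background λ. A solution within a relative error of 2e-05 in −log10 p was found for 100% of the 28524 and 28263 peaks, with largest errors of 1.27e-05 and 1.51e-05. The tolerance was set to 2e-05 after these errors had been seen, and 0.0001 had been used first. As a control, each peak was given the p of another peak of nearly equal fold. Then 2.0% and 0.85% of peaks matched at 2e-05, and 10.1% and 6.34% at 0.0001. On 5000 simulated peaks every count was recovered. Backgrounds above 20 were whole multiples of a step of 0.426 in replicate 1 and 0.536 in replicate 2, within 0.02 of a step, at 95.2% and 97.2% of such peaks. Over all peaks the shares were 37.4% and 35.3%. A step not fitted to the values gives 4% by chance, whereas this step was fitted to backgrounds of the same lists. The step was taken as the weight of 1 input fragment, and the estimate and its tolerance were set after the values had been seen. The counts are therefore inferred and are not the authors' own values. Library totals were not used here, so the depth of the libraries is not known. The median over the summits was 37 and 34 fragments. That is not a measure of depth, since such counts also depend on the fragment length used by the caller, which is not given. Intervals and tests on these counts cover counting error only.

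Peaks were called shared where they overlapped by at least 1 bp. Pairs were formed one to one by the largest overlap. The share expected by chance came from 1000 random placements of one list within chromosomes, with a one-sided permutation p. Correlations across pairs used 100000 permutations and are across peaks, which are not independent replicates. Intervals of shares are exact (Clopper-Pearson) 95% binomial intervals. They treat peaks as independent and do not measure how a share would vary between pairs of replicates or overlap rules. The counts of a pair were compared by a two-sided exact binomial test around the replicates' total ratio with Benjamini-Hochberg adjustment, which tests the 2 libraries and not a condition. Overlap and pairing were tested on simulated data, where 59.68% of peaks were copied and 59.68% were found shared. The extent of each of the 20 chromosomes was taken as the end of its last peak, since chromosome lengths were not used here. Outer regions are the first and the last 20% of that extent. Positions are 1-based in the build of the authors' files, whose name is not given in the sources used here.

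The rule for named sites, fixed in advance, took the genes next to the 10 shared peaks with the highest mean −log10 q, with peaks named by position where no gene was assigned. The same rule also named the gene GLYMA.13G153200, a list of embryo regulators and members of gene lists. Those parts could not be run. The 4 planned results on peak location, target genes, motifs at summits and gene lists needed a genome sequence or annotation of the files' build, and were not analysed here. The gene table at hand could not be matched to the files' build, since chromosome lengths and sequences were not compared. Of the peaks of both lists, 286 lie past its last gene on 5 chromosomes, by up to 1.11 Mb, which may or may not reflect another build. None of its coordinates were used.

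Alternatives set before the data were examined changed the q threshold, the fold threshold, the overlap rule, the number of peaks and the use of scaffolds. The chromosome positions, neighbour distances, inferred counts and backgrounds were added after the data had been examined. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.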

Results

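The data describe the binding of the GLYMA.13G153200 protein in soybean embryos at early maturation, the stage at which seeds begin to fill with storage reserves. The peak names call the target ABI5, the name of a bZIP transcription factor that acts in abscisic acid signalling in seeds. The stated purpose of the series is to locate its binding sites. The 4 samples comprise 2 ChIP and 2 input samples, and the values below come from 1 peak list per ChIP replicate. There is no second condition, so no comparison between conditions was made.

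Peaks, read here as binding, were called at a large number of sites in each replicate. The series holds no sample with a control antibody or without the protein. Whether the antibody also precipitated other chromatin was therefore not tested. Replicate 1 had 28524 peaks covering 13.4 Mb and replicate 2 had 28263 peaks covering 10.8 Mb. Median fold enrichment over the local background was 4.52 in replicate 1 and 4.78 in replicate 2. The central 90% of peaks, from the 5th to the 95th percentile, ran from 2.97 to 11.95 in replicate 1 and from 3.09 to 12.03 in replicate 2. The highest fold was 67.4 and 66.6. Peaks were wider in replicate 1, with a median of 421 bp against 348 bp, and the narrowest peak was 266 bp against 224 bp. The narrowest width may be a setting of the caller, whose options are not given. The differences in width and covered length are therefore not read as differences in binding. Unplaced scaffolds held 178 and 160 of the peaks. The inferred number of fragments over a summit had a median of 37 in replicate 1 and 34 in replicate 2, and no peak had fewer than 18 and 17.

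Most sites were found in both replicates. Of the peaks of replicate 1, 71.4% (95% interval 70.9 to 71.9) overlapped a peak of replicate 2, and 73.1% (72.5 to 73.6) of the peaks of replicate 2 overlapped one of replicate 1. Random placement gave 2.62% ± 0.094 (SD over 1000 placements) and 2.64% ± 0.096, and shifts of up to 50 kb, which keep the regional density, gave 5.77% ± 0.139 and 5.85% ± 0.136. The one-sided permutation p was 0.001 against each, the smallest that 1000 draws can give. The lists formed 20335 one-to-one pairs, called shared peaks here. The 2 lists together marked 36099 distinct regions. The summits of a pair lay close together, with a median distance of 38 bp and 90% of pairs within 128 bp.

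Strong sites were shared far more often than weak ones. In the weakest decile of replicate 1 by −log10 q, 38.1% of peaks were shared, against 98.4% in the strongest decile. In replicate 2 the values were 52.7% and 99.8%. Shared peaks had a median fold of 5.07 in replicate 1 and 5.38 in replicate 2, and the 8158 and 7613 peaks without a partner had medians of 3.79 and 4.07. Among peaks with −log10 q of at least 30, 116 of 4724 (2.46%) in replicate 1 and 55 of 4669 (1.18%) in replicate 2 had no partner. The strongest of these, chosen after its values were seen, lay on chromosome 7 at 3600074 to 3600897. It had a fold of 18.4 and 147 fragments in replicate 1, and the nearest summit of replicate 2 was 4546 bp away.

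**Figure D1:**
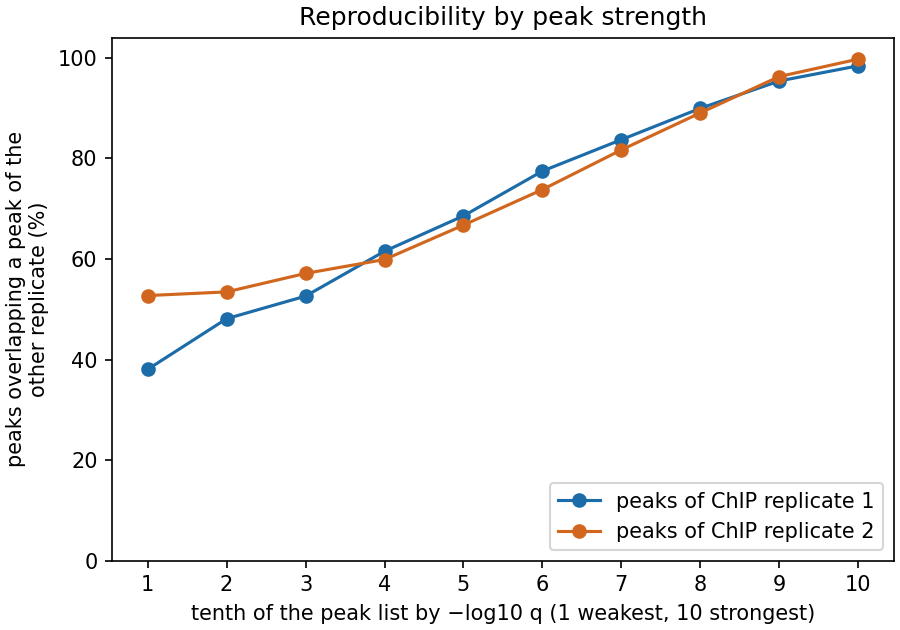
Share of peaks that overlap a peak of the other replicate (percent, y axis) by decile of each list ranked by −log10 q (x axis, 1 weakest), one line per ChIP replicate. The share rises from 38.1% to 98.4% in replicate 1 and from 52.7% to 99.8% in replicate 2.

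The 10 sites with the highest mean −log10 q had a fold of 53.6 to 64.7 over background (mean of n = 2). They lay on 7 chromosomes, and the summits of the replicates were at most 21 bp apart. The first was on chromosome 18 at 57421164 to 57422642, with a fold of 64.7 ± 2.79 (SD, n = 2) and 524 and 434 fragments. The second lay on chromosome 8 at 47622174 to 47623475, with 58.1 ± 1.498. The next sites were on chromosome 4 at 7931639 to 7933584 (60.5 ± 1.95), chromosome 6 at 7253141 to 7254997 (64.2 ± 3.58) and chromosome 2 at 40344950 to 40345973 (58.2 ± 0.15). Chromosome 14 held a site at 44869370 to 44870702 (55.8 ± 3.93) and another at 44735383 to 44736482 (53.6 ± 9.69). Chromosome 13 held a site at 26321522 to 26322491 (60.1 ± 10.3) and one at 14062892 to 14063805 (55.1 ± 16.0). Another site was on chromosome 6 at 48745845 to 48746721 (54.5 ± 8.79). With SDs of up to 16.0 the order of these folds is not resolved. The fragment counts of the 10 sites came to between 79.5% and 98.5% of 2 fragments per bp of the narrowest peak, which is 532 in replicate 1 and 448 in replicate 2. No peak exceeded that number. The genes at these sites were not analysed here.

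The strength of shared sites was moderately similar between replicates. Across the 20335 pairs, Spearman's rho of fold was 0.53 and Pearson's r of log2 fold was 0.64. For −log10 q, rho was 0.55 and r was 0.78. The permutation p was 1e-05 for each of the 4 correlations, the smallest that 100000 permutations can give, and adjustment over 4 equal values leaves it at 1e-05. The pairs are peaks and not independent replicates. Among 20100 pairs with an inferred background of at most 20 in both replicates, 3036 (15.1%) had fragment counts that differed beyond counting error (exact binomial test, adjusted p under 0.05). Of these, 1430 were higher in replicate 1 and 1606 in replicate 2, relative to the total ratio of 0.19 on the log2 scale. Each count was taken at the replicate's own summit, and the 75th percentile of the summit distance over all pairs was 73 bp. The counts of a pair therefore need not cover the same bases, which the binomial test does not allow for. The mean log2 ratio of replicate 1 to replicate 2 was 0.13 at 30 to 50 fragments, 0.45 at 100 to 200, 0.57 at 200 to 400 and 0.34 in the 11 pairs at 400 to 600. The SD of the log2 count ratio was 0.72 at 70 to 100 fragments, where counting gives 0.23, and 0.37 at 200 to 400 fragments, where counting gives 0.13. In the 11 pairs at 400 to 600 fragments it was 0.073, below the 0.098 of counting. Counts in that class lie near 532 in replicate 1 and 448 in replicate 2, which no peak exceeded. That may narrow the range of ratios, so the 0.073 does not show agreement closer than counting. Below 30 fragments the SD was 0.35 against 0.40. There both peaks had to pass the caller's threshold, which also narrows the range of ratios, so these values cannot be compared.

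**Figure D2:**
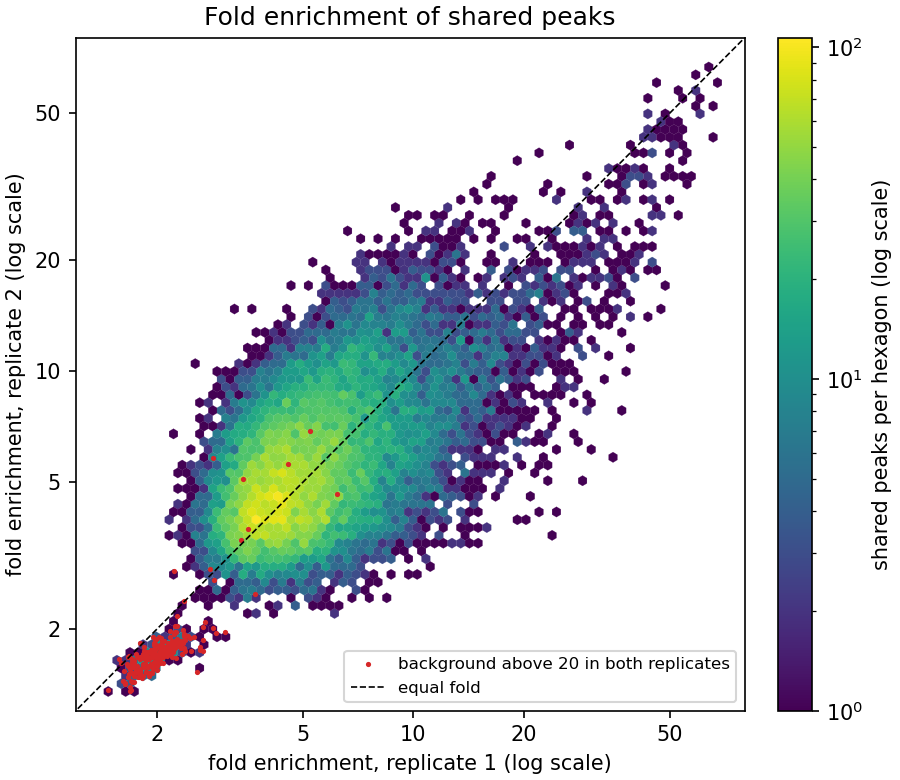
Fold enrichment of the 20335 shared peaks in replicate 1 (x axis) and replicate 2 (y axis), both log scales, as hexagons coloured by number of peaks on a log scale. The dashed line marks equal fold, and red points are shared peaks with an inferred background above 20 in both replicates, most of which lie at the lowest folds.

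A small set of sites had a high background. The inferred local background was above 20 fragments at 314 peaks (1.101%) of replicate 1 and 250 (0.885%) of replicate 2, against medians of 7.02 and 5.90 over all peaks. Their median fold was 2.04 and 1.71.

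Shared sites were concentrated toward chromosome ends. The outer regions, 20% of the extent at each end, held 37.1 ± 5.74 shared peaks per Mb and the inner part 11.3 ± 6.91 (SD over 20 chromosomes), a ratio of 3.29. The outer regions were denser on 19 of 20 chromosomes (exact two-sided sign-flip permutation p = 3.81e-06), and held 69.0% of the 20217 shared peaks on chromosomes. The exception was chromosome 13, with 26.7 per Mb in the outer regions and 35.2 in the inner part. The same chromosome had the highest overall density, 31.8 per Mb, and chromosome 18 the lowest, 16.1 per Mb. These counts departed from chromosome extent by a chi-square of 841, against at most 59.9 in 100000 random draws (permutation p = 1e-05, the smallest possible). The draws treat peaks as independent, while bins of 1 Mb held 1 shared peak at the 10th percentile and 52 at the 90th. Clustering within chromosomes alone can raise the chi-square, so this p does not show a difference between whole chromosomes. The median fold of all peaks stayed between 4.49 and 4.61 in replicate 1, and between 4.70 and 4.89 in replicate 2, across 10 equal parts of the chromosomes. Gene density and mappability along the chromosomes were not used here.

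The densest bins of 1 Mb were on chromosome 6 from 3 to 4 Mb, with 86 shared peaks, and on chromosome 11 from 3 to 4 Mb, with 85. The median over 956 bins was 13, and 52 bins had none.

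**Figure D3:**
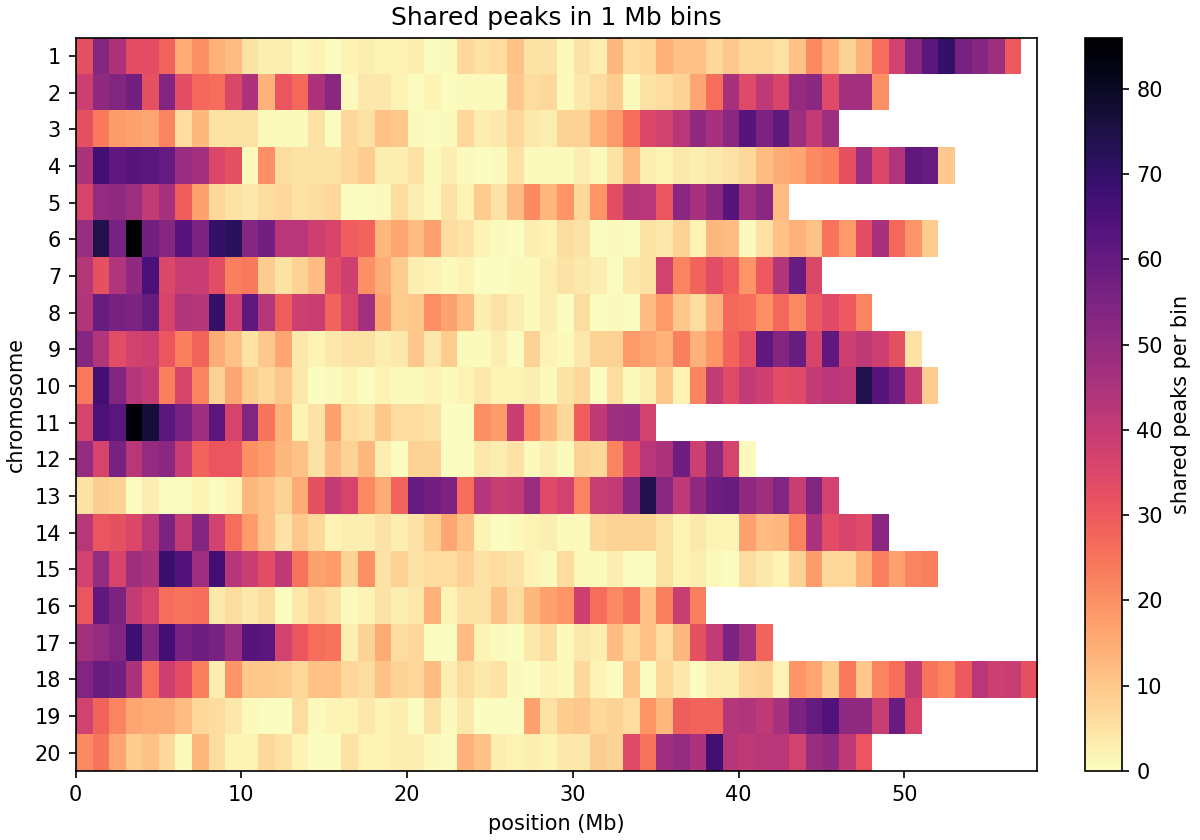
Number of shared peaks in each 1 Mb bin (colour) by position in Mb (x axis) on the 20 chromosomes (rows). Dark bins lie toward the ends on most chromosomes, while chromosome 13 has few shared peaks at its start and many through its middle and far end.

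Sites also lay close to each other. Of the shared peaks on chromosomes, 19.5% had another within 2 kb, against 8.47% after random placement and 15.5% ± 0.337 (SD over 1000 draws) after shifts of up to 50 kb, which keep the regional density. The permutation p was 0.001 for both, the smallest possible. Each peak was shifted on its own, so density that varies over stretches shorter than the shifts is not kept. Neighbours are separate called intervals, and the smallest gap was 84 bp in each list. An enriched region that the caller split would therefore count as separate sites. In 4 windows of 20 kb there were 8 shared peaks, on chromosomes 6, 8, 11 and 19. The window on chromosome 6, from 48735335 to 48753233, includes the named site at 48745845. Its 8 peaks had mean folds of 3.61 to 54.5. Beside that site were peaks of 30.5 ± 9.23 at 48744014 to 48744809 and of 26.5 ± 3.53 at 48743083 to 48743805. Another peak, at 48725864 to 48726697, had a fold of 47.6 ± 6.12.

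**Figure D4:**
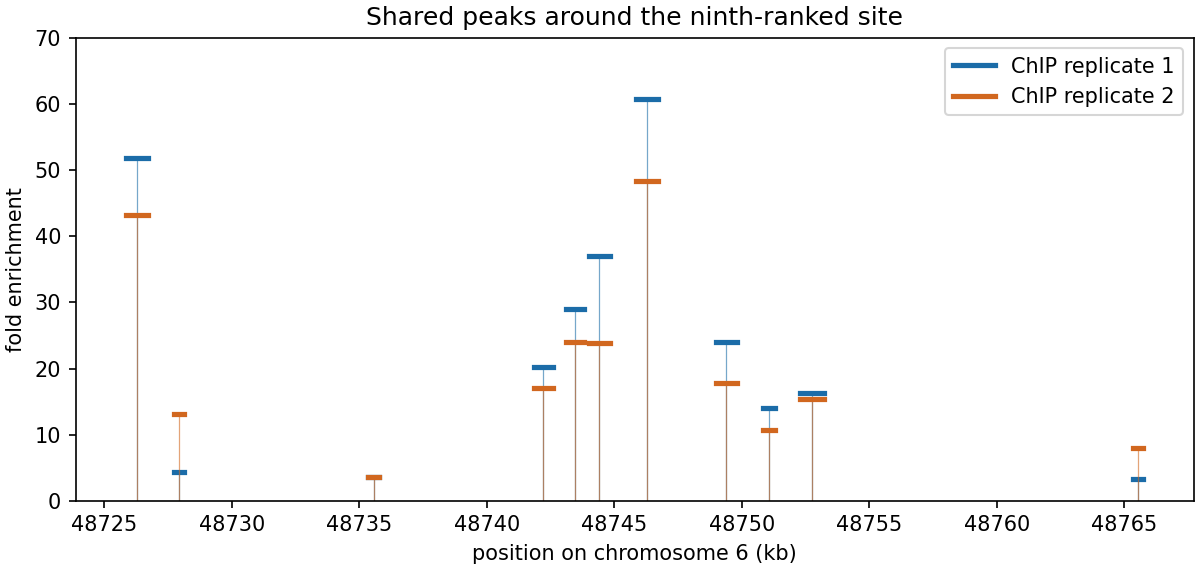
Shared peaks on chromosome 6 from 48725864 to 48765723 (x axis, kb) with fold enrichment (y axis) in each ChIP replicate; each bar spans the shared peak and sits at its fold. The site at 48745845 reaches 60.7 in replicate 1 and 48.3 in replicate 2.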

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

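The alternatives for chromosome ends, close neighbours, local shifts and high background were chosen after the data had been seen, and the others before. Of 41 values under alternatives, 40 were labelled as kept. Counts of peaks have no direction or threshold and only had to stay within a set factor of their main value. The other values had to keep their direction and their side of the threshold. Under local shifts the values are the same by construction, and only the chance level changes. The exception was the number of shared peaks, 20335, which became 9254 when only the stronger 50% of peaks by −log10 q, counted on the smaller list, were kept in each replicate, an alternative that by construction has fewer peaks. The share of replicate 1 peaks that were shared ran from 60.7% (summits within 100 bp) to 71.4%, and that of replicate 2 from 61.3% to 73.1%. Taking all peaks of one replicate in place of shared peaks gave 68.9% and 69.2% in the outer regions. No paired analysis was possible because the input samples have no values here and the lists belong to one group. Alternatives for peak location, target genes, motifs and gene lists were not run, since they need a genome or annotation of the files' build. With 2 replicates, the SD of a fold rests on a single difference, and weak peaks near 17 or 18 fragments are limited by counting error.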

Other observations

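The tests of capped sites, counting spread, background ratio, neighbouring ratios, the number of modes, the refit that allows for missing pairs, and the chromosome position of the pairs were chosen after the result had been seen.

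Over deciles of shared peaks by mean fold, the share with another shared peak within 2 kb ran from 16.5% in decile 5 to 21.8% in decile 10, the strongest, and was 20.1% in the weakest. Of pairs with 70 to 200 fragments, those whose log2 count ratio lay more than 0.2 above the replicates' total ratio (0.19 on the log2 scale) had 67.6% in the outer regions of chromosomes (1024 pairs), and those as far below it had 73.9% (858 pairs, two-sided Fisher's exact p = 0.0028, not adjusted). Measured from 0 in place of the total ratio, the shares were 66.6% (1208 pairs) and 74.0% (732 pairs, two-sided Fisher's exact p = 0.00065). Across 10 equal parts of the chromosomes the mean log2 ratio of pairs with 40 to 200 fragments varied only from 0.11 to 0.18.

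Shared peaks with a high background had low fold, for which no biological explanation was tested. Of the 235 shared peaks with a background above 20 in replicate 1, 99.1% were also high in replicate 2, but another 79 of the 314 such peaks of replicate 1 are in no pair, and counting them as not high gives 74.2%. The control behind each list is not given in the sources used here, and a common control would fix this agreement, so sequence that collects input fragments in every library stays open. The largest background corresponded to 532 and 448 input fragments, equal to 2 per bp of the narrowest peak, which suggests a limit of 1 fragment per position and strand, and that may also compress the folds of the 10 strongest sites. At the 21 sites with a background near that limit the median fold ratio of replicate 1 to 2 was 1.17, but this does not bear on a limit on ChIP fragments, since their backgrounds alone, with fragments at the total ratio, give 1.205, close to the ratio of input weights of 1.26 that the limit predicts.

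Fragment counts of shared peaks of intermediate strength differed between replicates more than counting allows. Among 2226 pairs with 70 to 200 fragments, the SD of the log2 ratio was 3.34 times the counting SD, which decides nothing about its cause, since separate biological samples vary beyond counting noise by design. The ratio did not follow the ratio of backgrounds (rho −0.018). Neighbours 20 to 100 kb apart had an r of −0.012 (564 neighbours, 95% interval −0.095 to 0.071, permutation p = 0.78). That argues only against differences that extend over 20 to 100 kb, such as a large copy number change. Differences over shorter stretches are not covered by it. Over the wider set of pairs with 40 to 200 fragments, r at 20 to 100 kb was 0.020 (4250 neighbours). In that set 6 distance classes were examined. Those up to 1 kb, from 1 to 2 kb and from 2 to 5 kb had r of 0.22, 0.18 and 0.14 (adjusted permutation p = 0.032, 0.0014 and 0.00084), so the ratios of close neighbours did vary together. The other 3 had r of at most 0.020 (adjusted permutation p from 0.29). The ratios had modes at −0.49 and 0.57 (bootstrap p of a single mode 0.005, the smallest that 200 draws can give), what gives them stays open, and no biological explanation was tested.

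Some strong peaks of replicate 1 were missing from replicate 2. Of 4687 with a background of at most 20, 115 had no partner, against 0.0154 expected from counting error (Poisson range 0 to 0). That argues against counting error alone. It decides nothing about what else was at work, because the bound set in advance left out the variation between separate samples. The spread among shared peaks gave 66.1 (Poisson range 51 to 82), the test as first written, but that spread is too small because missing pairs are absent from it. A refit that allows for them, added after that result, gave 92.5 (74 to 112), only just below 115. Both numbers assume normal residuals, which the separate modes speak against, so they argue only weakly against the spread as the whole cause, and a mixed-up replicate and any biological explanation stay untested.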
